A study of Arabidopsis thaliana with 6 samples.

How the data were processed

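RNA structure was probed by DMS mutational profiling in 6 libraries of Arabidopsis thaliana leaves. Per the labels' protocols, plants 3 weeks old were treated with 1% DMS, or with water as the mock, for 30 min under vacuum, and nuclear RNA was extracted. Gene-specific primers were used to reverse transcribe 5 µg of nuclear RNA with a thermostable group II intron reverse transcriptase and to amplify each target, and the PCR products were mixed in equal amounts and cut to 50 to 200 bp before sequencing. Depth therefore does not measure the abundance of an RNA, and no molecular identifiers are mentioned in the labels. PCR reads are not independent molecules, so intervals given for shares of reads cover counting error only.

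The deposited files hold counts: per the file headers, the number of A, C, G and T base calls at each position of each amplicon, with the reference base. The authors' counts cover 5550 positions of 19 amplicons, of which 2656 are A or C in the transcribed strand. The submitters' processing notes name cutadapt, BWA, Picard and SAMtools 1.5, and their roles and the reference build are not given in the sources used here, so no genome coordinates are printed. Names of the 19 amplicons were looked up in a table of gene names (assembly TAIR10.1), and all 19 had a match. They are UBQ4 (AT5G20620), MYC2 (AT1G32640), MPK3 (AT3G45640) and 16 MIR genes, among them MIR159a (AT1G73687), MIR165a (AT1G01183), MIR168a (AT4G19395), MIR390a (AT2G38325) and MIR393b (AT3G55734).

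From the counts, coverage was taken as the sum of the 4 bases and the mismatch rate as the share of bases other than the reference. Median coverage per position was between 54600 and 80480, and a few positions of pri-miR390a had 0. Positions entered a test with a coverage of at least 100 in each library of the fit, a rate of at most 5% in both mocks and at least 10 mismatches. The first and last 26 nt of an amplicon were taken as primer ends after the data were examined, since their mean A/C rate with DMS was 0.0918% to 0.105%, against 1.67% to 2.06% inside. They were kept in the tests but left out of the region rates. Those region rates, and the tests of one region against another within a genotype, were set after the data were examined, whereas the fry sets compared between genotypes were set before. Folds were predicted with ViennaRNA 2.7.2 (minimum free energy) from the amplicon sequence. Mature miRNA positions were found by exact match of known mature sequences, which occurred once in each pri-miRNA, and the miRNA* was taken as their predicted pairing partners. The terminal loop is the set of unpaired nucleotides on the loop side of that duplex, bulges and internal loops included.

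Groups were Col mock (1 library), chr2 mock (1), Col DMS (2) and chr2 DMS (2). A/C positions were compared between chr2 and Col with edgeR 4.0.16 (quasi-likelihood test, R 4.3.3) on mismatch counts with log coverage and a size factor per library as offset, the size factor being the median ratio of rates over A/C sites (0.962 to 1.01). Most A/C positions were not above mock, so this factor rests largely on background rates and may miss a difference in the extent of modification. Factors from the mean rates of the mRNAs were 0.927 and 0.955 in the Col DMS libraries and 1.06 and 1.07 in those of chr2. DMS was compared with mock in a fit of all 6 libraries without size factor, and the difference of DMS responses with size factors. G/T positions were tested the same way as a control. Mean A/C rate (log2, scaled) and Gini index per pri-miRNA were tested with limma 3.58.1, and region groups with limma's fry on log2(rate + 0.001). Thresholds are a Benjamini-Hochberg adjusted p of 0.05. Single values per library were compared by two-sided exact permutation, whose smallest p with 2 libraries against 2 is 0.333. Regions were compared within a genotype by an exact two-sided sign-flip permutation over the 16 pri-miRNAs, on the log2 ratio of mean rates with 0.05% added, adjusted over 10 tests. Shares of single libraries carry 95% Wilson intervals. Python 3.11.15 with SciPy 1.17.1 was used for these.

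The rule for named items was fixed before the data were examined. It took pri-miRNAs past any test per pri-miRNA, the 8 with the most differing positions and 22 listed families, the 5 positions with the smallest p in each direction where fewer than 3 pass, and the 3 highest mean rates per genotype for DMS against mock. No pri-miRNA had a differing position, so the 8 were taken by smallest adjusted p. All 8 had 0.254 by edgeR, and ties were broken by the smallest unadjusted p, which the rule did not name.

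Alternatives were DESeq2 1.42.0, limma on log2 rates, no or other size factors, coverage minimums of 30 and 1000, no mismatch minimum, mock limits of 1% or none, other pseudocounts, mock subtraction, camera in place of fry, the partition-function fold, a replicate block, and leaving out each DMS library in turn. Leaving out primer ends, a size factor from the mRNAs, fits on mRNAs or pri-miRNAs alone and on all 19 amplicons were added after the data were examined. Every pair of DMS libraries was checked for identity by a chi-square statistic over A/C positions, which was at least 1128 per position, so none was a repeat of another within sampling noise.

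Replicates were compared by Pearson's r of log2(rate + 0.001) across A/C positions. The apparent number of cDNA templates was the sum over A/C positions of p1(1 - p2) + p2(1 - p1), divided by the sum of squared differences p1 - p2 between the replicates' rates, averaged over genotypes. Simulated numbers of 2, 30 and 400 were recovered as 2, 30.76 and 406.6 over 110 positions. Tests were checked on simulated counts. With the spread of these libraries, 0% of 2-fold, 4-fold and 8-fold changes were recovered over 2591 A/C positions. With a dispersion of 0.01, 100% were recovered, with 12 false calls among 2394 unchanged positions. On the 455 A/C positions of the mRNAs alone, 0% of 2-fold, 36.7% of 4-fold and 73.3% of 8-fold changes were recovered. Of 4 pri-miRNAs changed 2-fold, the test of the mean recovered 0% and fry 25% with the spread of these libraries.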

Results

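Chemical probing of RNA structure inside living leaves was measured in Arabidopsis thaliana, in the wild-type accession Columbia (Col) and in the chr2 mutant. CHR2, also called BRAHMA, is the ATPase of a SWI/SNF chromatin remodelling complex, and the series title links it to the folding of primary microRNA transcripts (pri-miRNAs) through SERRATE, a partner of the Dicer enzyme in the plant microprocessor. Dimethyl sulfate (DMS) methylates the pairing face of unpaired adenosines and cytidines. A reverse transcriptase that reads through the methyl group leaves a mismatch there, so the mismatch rate of A and C positions measures how open each was. G and T positions served as an internal control. The 6 libraries comprised 2 DMS-treated libraries of each genotype and 1 mock-treated library of each genotype. Each held 19 amplicons of 230 to 327 nt: 16 pri-miRNAs and parts of 3 mRNAs, UBQ4 (ubiquitin), MYC2 (a jasmonate transcription factor) and MPK3 (a MAP kinase). Depth was 453222421 base calls in the Col mock and 342449353 in the chr2 mock. The Col DMS libraries held 447512861 and 446281801 base calls, and the chr2 DMS libraries 451340108 and 384566131. Positions are counted from 1 at the 5' end of each amplicon, in the transcribed strand. The labels number the DMS libraries but do not say that they came from separate plants, so p-values measure only the spread between these libraries.

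The first comparison asked where DMS raised the mismatch rate above the mock level. Over 2645 A/C positions the mean rate with DMS was 1.48% ± 0.134 (SD, n = 2) in Col and 1.66% ± 0.0600 (SD, n = 2) in chr2, against 0.0668% in each single mock library. The median over the same positions was 0.0749% ± 0.0157 in Col and 0.0751% ± 0.00425 in chr2 (SD, n = 2 each), only 2.04 and 1.99 times that of the mock. Positions above mock were most frequent in the mRNAs: in Col, 120 in MYC2 (72.7% of those tested), 85 in UBQ4 (65.4%) and 56 in MPK3 (35.0%). Among the pri-miRNAs they were most frequent in pri-miR159a, whose miRNA represses MYB transcription factors, with 23 of 127 in Col and 21 in chr2. In pri-miR168a, the precursor of the miRNA that represses AGO1, 16 of 145 passed in Col and 20 in chr2, and in pri-miR166a 16 of 134 passed in each genotype. None passed in either genotype in pri-miR390a, pri-miR319a, pri-miR165a, pri-miR164b or pri-miR160c.

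By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 344 of 2597 A/C positions were above mock in Col and 337 in chr2, and 2 were below it in each. Of these, 310 were above mock in both genotypes. In the mRNAs 249 were shared, where independent lists would share 146, and in the pri-miRNAs 61, where independent lists would share 3.22. Both contrasts used the same estimate of spread per position, so part of this overlap may be shared error. No G/T position of 2840 passed in either genotype, with 190 in Col and 208 in chr2 at an unadjusted p under 0.05. Mean rates at T were nonetheless 0.1165% to 0.176% in the DMS libraries, against 0.0496% and 0.0509% in the mocks. At G they were 0.128% to 0.180%, against 0.112% and 0.116%. The median at T lay between 0.0290% and 0.0308% in every library. DESeq2 called 978 and 982 A/C positions and 50 and 48 G/T positions. Without any single DMS library, edgeR called no A/C position, since each mock had 1 library and the spread came from the DMS pairs alone.

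Position 208 of pri-miR159a repeated closely between replicates. This position, an A of the miRNA left unpaired in the predicted fold, had a rate of 12.5% ± 0.0567 (SD, n = 2) in Col and 11.6% ± 0.0652 (SD, n = 2) in chr2. Its mock rates were 0.0403% (95% Wilson interval 0.0273 to 0.0595) in Col and 0.110% (0.0844 to 0.144) in chr2, and edgeR's adjusted p was 0.0382 and 0.0482. Position 50, an unpaired A of the miRNA* strand, varied more and reached 9.57% ± 2.93 (SD, n = 2) in Col and 8.27% ± 0.335 (SD, n = 2) in chr2. In pri-miR168a, position 112, an A that the fold predicts to be paired, reached 8.89% ± 3.58 in Col and 9.67% ± 1.72 in chr2 (SD, n = 2 each). These 3 positions were chosen after their values were seen. Among positions within the mock limit, the 3 with the highest mean rate did not pass in either genotype, because their replicates lay far apart. In Col all 3 belonged to pri-miR393b, and position 246 had 1.48% in replicate 1 and 99.9% in replicate 2 (edgeR's adjusted p = 0.289). In chr2 all 3 belonged to pri-miR390a, and position 196 had 99.9% in replicate 1 and 32.8% in replicate 2 (edgeR's adjusted p = 0.479). In Col replicate 2 this position had 63.4%.

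**Figure D1:**
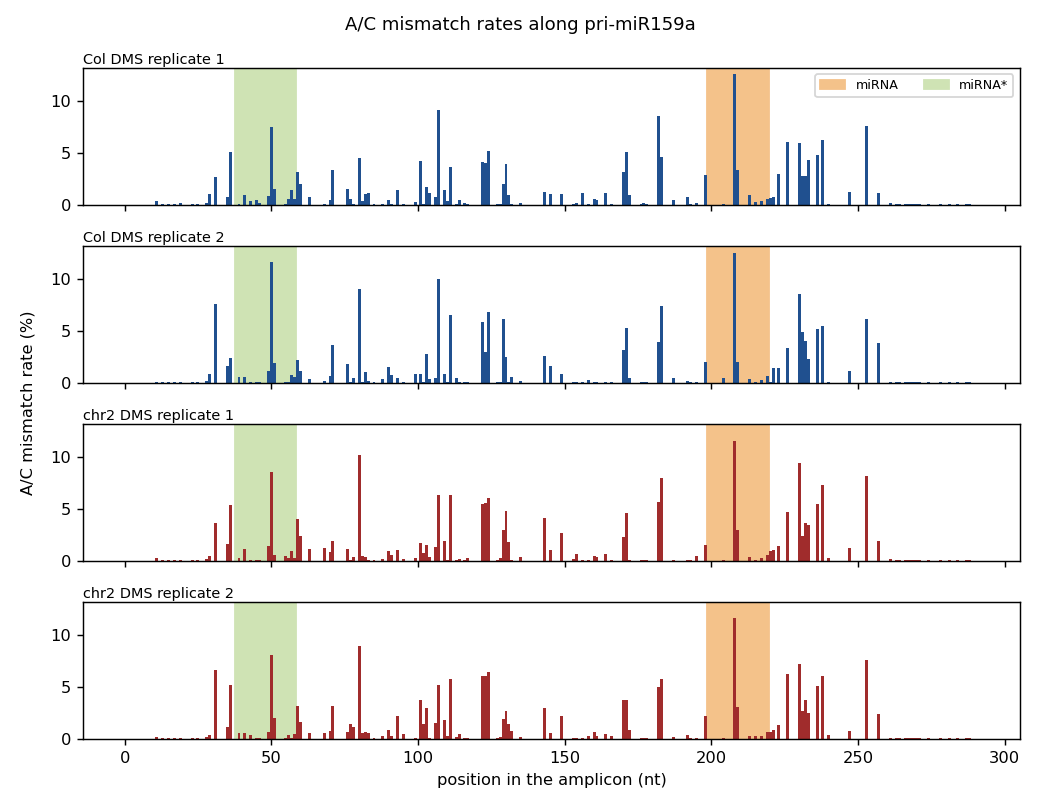
Mismatch rate in percent at each A or C position along the pri-miR159a amplicon, 1 panel for each of the 4 DMS libraries, with the miRNA and miRNA* shaded. Position 208 in the miRNA stands between 11.5% and 12.6% in every panel.

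The next question was how the rates followed the predicted fold of the pri-miRNAs. With primer ends left out, predicted unpaired positions of the pri-miRNAs had a mean A/C rate of 2.87% ± 0.310 in Col and 3.07% ± 0.0491 in chr2 (SD, n = 2 libraries each), and paired ones 0.931% ± 0.112 and 1.14% ± 0.167. Unpaired positions between the strands of the duplex, called terminal loops here although they include bulges and internal loops, had 3.00% ± 0.144 in Col and 3.39% ± 0.0836 in chr2, close to unpaired positions as a whole. The miRNA strand had 0.742% ± 0.130 in Col and 0.742% ± 0.229 in chr2, and the miRNA* strand 0.467% ± 0.0157 and 0.494% ± 0.0745. Stem positions between the duplex and the loop had 0.729% ± 0.0783 in Col and 0.800% ± 0.0884 in chr2. Sequence 5' of the duplex had 2.01% ± 0.101 and 2.07% ± 0.0587, and sequence 3' of it 2.32% ± 0.714 and 2.98% ± 0.429. Mock rates in these parts lay between 0.0501% and 0.0949%. The equal means of the miRNA strand depend on the mock limit of 5%, which removed 1 of its positions, in pri-miR165a: without the limit they were 0.738% ± 0.129 in Col and 1.05% ± 0.218 in chr2, with 1.21% in chr2 replicate 1 in place of 0.580%. Loops then had 2.98% ± 0.143 in Col and 3.65% ± 0.467 in chr2.

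Predicted unpaired positions exceeded paired ones in all 16 pri-miRNAs in both genotypes, on average 3.20-fold in Col and 2.74-fold in chr2 (exact sign-flip permutation, adjusted p = 0.000102 for each). Terminal loops exceeded the miRNA duplex in 14 of 16 pri-miRNAs in Col (4.73-fold, adjusted p = 0.000712, exact permutation) and in 16 of 16 in chr2 (5.85-fold, adjusted p = 0.000102). Loops exceeded the sequence 5' of the duplex in 13 of 16 pri-miRNAs in chr2 (1.89-fold, adjusted p = 0.00231, exact permutation), a call lost without chr2 replicate 1 (exact permutation, adjusted p = 0.139) and without chr2 replicate 2 (0.529). By the same exact permutation test, the contrast in Col (adjusted p = 0.470), and loops against sequence 3' of the duplex in Col (0.541) and chr2 (0.298), did not pass. Loops exceeded the stem between duplex and loop in 13 of 16 pri-miRNAs in Col (3.94-fold, adjusted p = 0.000610, exact permutation) and in 15 of 16 in chr2 (5.41-fold, adjusted p = 0.000153). In Col the calls of loops over the duplex and over this stem were lost without replicate 1 (exact permutation, adjusted p = 0.155 and 0.312). These region tests were chosen after the region means were seen, and since the loops hold unpaired positions by definition while the other parts are paired or mixed, they do not separate location from pairing. Whether these contrasts differed between genotypes was not tested here.

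**Figure D2:**
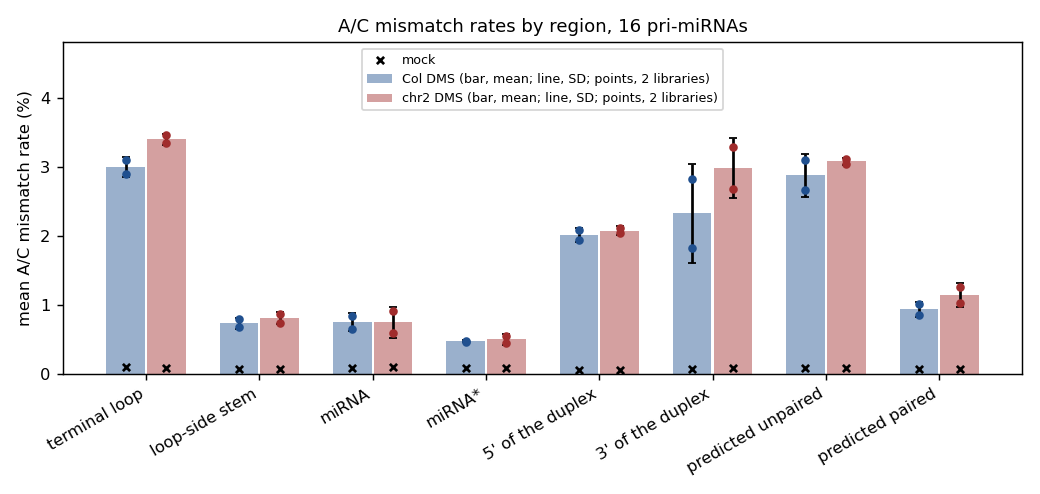
Mean A/C mismatch rate in percent by region over the 16 pri-miRNAs, primer ends and positions above the mock limit left out; bars are means, lines the SD and points the 2 DMS libraries of each genotype, with crosses for the mock. Terminal loops stand at 3.00% in Col and 3.39% in chr2, above the miRNA at 0.742% in both, and hold unpaired positions only.

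Over all positions including primer ends, the area under the curve that separates predicted unpaired from paired A/C was 0.564 ± 0.0194 in Col and 0.561 ± 0.0143 in chr2 (SD, n = 2 each; two-sided exact permutation p = 1). In the mocks it was 0.472 in Col and 0.478 in chr2. Without primer ends it was 0.629 ± 0.0334 in Col and 0.629 ± 0.0170 in chr2 with DMS (SD, n = 2 each). In the 3 mRNAs it was 0.632 ± 0.000688 in Col and 0.623 ± 0.00223 in chr2, and without primer ends 0.665 ± 0.000907 and 0.656 ± 0.00215 (SD, n = 2 each). The libraries of the genotypes did not overlap there, with chr2 lower (two-sided exact permutation p = 0.333 for each, the smallest possible), and the mRNA values were computed after the data were examined.

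The main comparison asked whether loss of CHR2 changed pri-miRNA structure. No A/C position of 2594 passed edgeR's test between chr2 and Col with DMS, and 110 had an unadjusted p under 0.05. The 5 positions higher in chr2 with the smallest p included 2 in pri-miR393b, whose miRNA represses auxin receptors. Position 138 of pri-miR393b had 0.0212% ± 0.00642 in Col and 5.36% ± 0.374 in chr2, and position 58 had 0.0418% ± 0.00656 and 5.04% ± 1.18 (SD, n = 2 each). In pri-miR168b, position 181 had 0.0262% ± 0.000691 in Col and 2.50% ± 0.213 in chr2. In pri-miR156b, whose miRNA controls the juvenile phase through SPL genes, position 153 of the miRNA* had 0.0404% ± 0.000456 in Col and 7.15% ± 2.85 in chr2. Position 135 of pri-miR160a, a precursor whose miRNA represses auxin response factors, had 0.0242% ± 0.00444 in Col and 2.32% ± 0.430 in chr2.

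Of the 5 positions lower in chr2 with the smallest p, 2 were in pri-miR160a and 2 in pri-miR167b, which also acts on auxin response factors. Position 47 of pri-miR160a had 2.32% ± 0.223 in Col and 0.0268% ± 0.00420 in chr2, and position 133 had 2.78% ± 1.04 and 0.0213% ± 0.00127 (SD, n = 2 each). Position 50 of pri-miR167b had 2.83% ± 0.0626 in Col and 0.0185% ± 0.000365 in chr2, and position 235 had 4.40% ± 2.13 and 0.0250% ± 0.00120. Position 106 of pri-miR166b, whose miRNA represses HD-ZIP III genes, had 8.17% ± 1.56 in Col and 0.0353% ± 0.00393 in chr2. All 10 had an edgeR adjusted p of 0.254 and did not pass. In each, the lower genotype had a mean rate under 0.05%.

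DESeq2 called 288 A/C positions, 155 higher and 133 lower in chr2, among them these 10. It also called 235 of 2833 G/T control positions, where edgeR called none with 112 at an unadjusted p under 0.05. When the 4 DMS libraries were regrouped by replicate number, DESeq2 called 323 A/C positions, and with the numbers crossed between genotypes 281. Limma on log2 rates called no A/C position, with 128 at an unadjusted p under 0.05. For the DMS response over mock, no A/C position of 2597 differed between genotypes by edgeR, with 87 at an unadjusted p under 0.05, and DESeq2 called 52.

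Mean rates of whole pri-miRNAs were compared next, by a test that recovered 0% of 2-fold changes in simulations with the spread of these libraries. Of the 22 miRNA families listed before the data were examined, 9 were represented, by the 16 pri-miRNAs. None passed limma's test of the mean A/C rate, and none had an unadjusted p under 0.05. With the main size factor, 11 means were higher and 5 lower in chr2. This lean depended on the size factor. With one from the mRNAs, pri-miR319b (ratio 0.966), pri-miR168a (0.988), pri-miR166a (0.951) and pri-miR159a (0.919) turned lower, and again none passed. The libraries of the genotypes did not overlap in 6 of 16, with chr2 higher in 5 and lower in 1, where chance alone would give 5.33. Pri-miR165a counts among the 5 lower means, and not among these 6, only because of the mock limit, as given below. In the family of miR159 and miR319, pri-miR159a had 1.51% ± 0.0738 in Col and 1.52% ± 0.0206 in chr2 after scaling (SD, n = 2 each), a ratio of 1.01 with a 95% interval of 0.765 to 1.32. Pri-miR159b had a ratio of 1.24 (0.875 to 1.76), pri-miR319b 1.06 (0.805 to 1.39) and pri-miR319a 0.969 (0.279 to 3.37). In the family of miR165 and miR166, pri-miR166a had a ratio of 1.04 (0.780 to 1.39) and pri-miR166b 1.12 (0.710 to 1.75). Pri-miR165a had 0.0526% and 2.86% in its 2 chr2 libraries, so its interval spanned 0.00225 to 33.7. The 0.0526% leaves out 5 positions with 99.1% to 100.0% in chr2 replicate 1, removed by the mock limit. With them, both chr2 libraries would lie above both Col libraries, which had 0.977% and 2.03%. The ratio was 1.08 (0.753 to 1.55) in pri-miR168a, 1.22 (0.889 to 1.67) in pri-miR168b, 0.955 (0.588 to 1.55) in pri-miR160a and 1.11 (0.251 to 4.91) in pri-miR160c. It was 0.858 (0.617 to 1.19) in pri-miR156b, 1.30 (0.804 to 2.11) in pri-miR164b and 0.915 (0.571 to 1.47) in pri-miR167b. Pri-miR390a, whose miRNA triggers trans-acting siRNA production, had 1.99 (0.743 to 5.32) and pri-miR393b 1.13 (0.470 to 2.73). In pri-miR390a, Col replicate 2 and chr2 replicate 1 shared positions with high rates, described below.

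The Gini index, which measures how unevenly reactivity is spread along an RNA, passed limma's test in none of the 16 pri-miRNAs, with none at an unadjusted p under 0.05. In pri-miR156b it was 0.913 ± 0.00946 in Col and 0.850 ± 0.0124 in chr2 (SD, n = 2 each; limma adjusted p = 0.675). With all 19 amplicons in the fit the mRNAs did not pass either (limma adjusted p = 0.736 in UBQ4, 0.710 in MYC2 and 0.710 in MPK3). None of 7 region groups moved one way by limma's fry, with 1 at an unadjusted p under 0.05, sequence 3' of the duplex (adjusted p = 0.235; adjusted p = 0.372 with an estimated correlation). The miRNA* strand had the same fry adjusted p of 0.235, and a smaller one than 3' sequence with no size factor (0.199 against 0.893), without primer ends (0.308 against 0.646) and with a pseudocount of 0.0001 (0.241 against 0.300). Terminal loops had a fry adjusted p of 0.603 and the miRNA strand 0.428. For predicted unpaired positions and for sequence 3' of the duplex, fry's direction was down while the mean log2 ratio was 0.04 and 0.07. None of the 16 pri-miRNAs taken as sets moved one way by fry, with 1 at an unadjusted p under 0.05, pri-miR165a, lower in chr2. That set lacks 5 positions removed by the mock limit, which were near 100% in chr2 replicate 1, and it was not tested with them. Tested for change in either direction, 6 of the 16 pri-miRNAs passed between the genotypes, but 14 passed when the same libraries were grouped by replicate number and 6 with the numbers crossed. Among the region groups, predicted unpaired positions (adjusted p = 0.00684) and sequence 5' of the duplex (0.00318) passed fry in either direction. Regrouped libraries were not tested for them. Region groups depended on single libraries: 1 passed without Col replicate 1 and 6 without Col replicate 2, all lower in chr2 by fry, and 2 passed without chr2 replicate 1 and 5 without chr2 replicate 2, all higher. Fry's direction and the mean again differed in sign in some of these, such as terminal loops without Col replicate 1 (mean log2 ratio 0.36).

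In the mRNAs the mean rates were higher in chr2 without scaling. UBQ4 had 1.92% ± 0.0104 in Col and 2.19% ± 0.00605 in chr2, MYC2 2.05% ± 0.0769 and 2.35% ± 0.0696, and MPK3 2.18% ± 0.0483 and 2.42% ± 0.0525 (SD, n = 2 each). None passed limma's test (adjusted p = 0.300 each), and reads of UBQ4 may include other ubiquitin genes, so its values are uncertain. Over all amplicons the chr2 mean was 1.12 times that of Col (two-sided exact permutation p = 0.333, the smallest that 2 libraries against 2 can give).

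The agreement of replicates set what could be seen. The correlation of log2 A/C rates between replicates averaged 0.934 in MYC2, 0.899 in UBQ4 and 0.456 in MPK3. Among pri-miRNAs it was 0.851 in pri-miR159a and 0.687 in pri-miR168a, and fell to 0.0846 in pri-miR165a and -0.0132 in pri-miR160c. These are correlations across positions of an RNA, which are not independent replicates. Over the 16 pri-miRNAs the median was 0.418 within a genotype and 0.419 across genotypes. A rate above 1% in all 4 DMS libraries was found at 71.6% of 387 A/C positions of the mRNAs and at 9.19% of 1784 of the pri-miRNAs. In simulations with the spread of these libraries, the edgeR test over 2591 A/C positions recovered 0% of 8-fold changes, so a difference of that size at a single position was not detectable by that test. With the mRNAs fitted alone, 73.3% of 8-fold and 36.7% of 4-fold changes were recovered over 455 A/C positions, and edgeR called 0 of them between the genotypes, with 22 at an unadjusted p under 0.05.

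**Figure D3:**
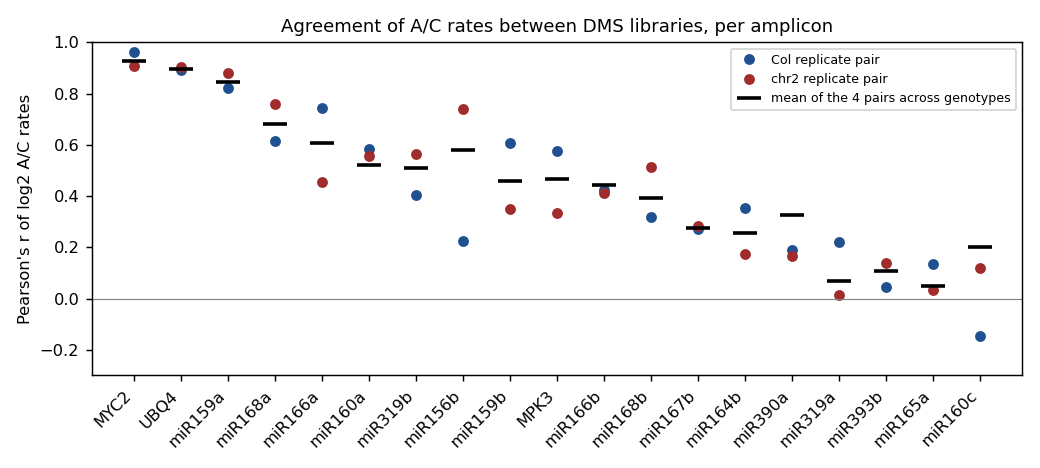
Pearson's r of log2 A/C mismatch rates across positions for each amplicon; points are the replicate pairs of Col and chr2, and dashes the mean of the 4 pairs across genotypes. MYC2 stands at a mean of 0.934 and pri-miR160c at -0.0132.

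In pri-miR165a the positions with high rates differed from library to library. In chr2 replicate 1, 5 positions (32, 102, 143, 209 and 252) had rates of 99.1% to 100.0%, and in chr2 replicate 2, positions 56, 154, 217 and 268 had 99.6% to 99.9%. In Col replicate 2, positions 93, 175 and 184 had 84.2% to 85.4%, and in Col replicate 1 positions 57, 80 and 82 had 34.7%, 37.1% and 50.5%. Not all of these were at background elsewhere: position 56 had 2.39% and position 184 had 1.91% in Col replicate 1, and position 175 had 2.65% in the Col mock. The 5 positions of chr2 replicate 1 exceeded the mock limit of 5% in the Col mock and were left out of the tests, so the mean rate of pri-miR165a in that library was 0.0526%.

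**Figure D4:**
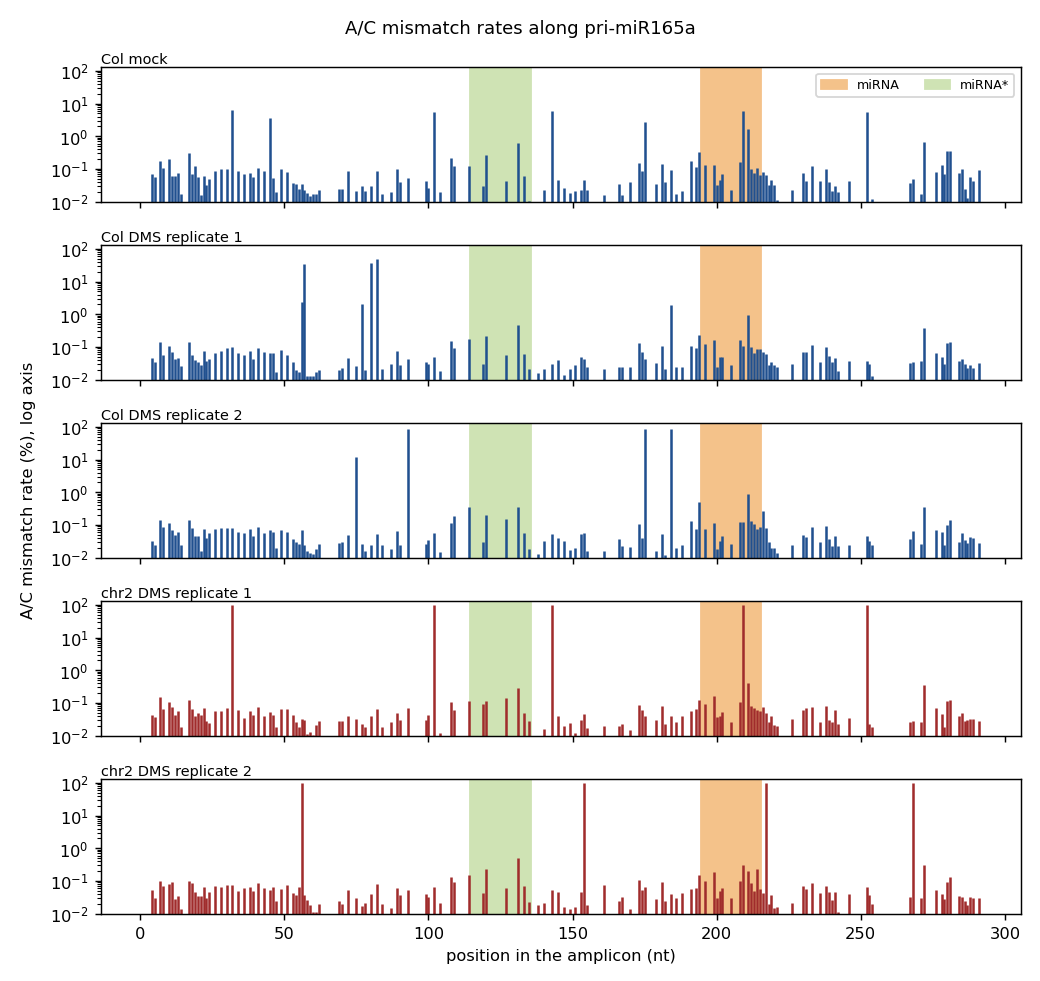
Mismatch rate in percent, on a log axis, at each A or C position along the pri-miR165a amplicon in the Col mock and the 4 DMS libraries, with the miRNA and miRNA* shaded. The 5 positions near 100% in chr2 replicate 1 stand at 5.53% to 6.52% in the Col mock.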

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

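The tests of pri-miR165a in this part were chosen only after the result was seen. A signal stood out in data that the comparisons left aside: 5 A/C positions of pri-miR165a, left out because of the mock limit, had mismatches in the untreated Col library. Their rates there were 6.52% at position 32 (95% Wilson interval 6.31 to 6.73), 5.60% at 102 (5.39 to 5.82), 6.08% at 143 (5.82 to 6.35), 5.93% at 209 (5.63 to 6.23) and 5.53% at 252 (5.25 to 5.82). These are the 5 positions that read 99.1% to 100.0% in chr2 DMS replicate 1. The highest rate at them in the other 4 libraries was 0.311%, which argues against a fixed error or modification of these positions. The highest Col mock rate was 1.179 times the lowest, the near-common level that a single carried-over molecule would give. Within pri-miR165a, carryover of amplified material between the libraries is therefore a candidate explanation for these 5 positions only. Of the 3 positions at 84.2% to 85.4% in Col DMS replicate 2, position 175 had 2.65% (2.47 to 2.83) in the Col mock, but 93 had 0.0514% and 184 had 0.0960%, unlike a carried-over molecule with all 3. Positions 45 and 117 had 3.72% and 3.30% in the Col mock and at most 0.0741% and 0.128% in the other 5 libraries, so none of those libraries supplies them. Positions of pri-miR319a and pri-miR393b that were high in chr2 DMS replicate 1 alone had at most 0.0583% in the Col mock, and no biological explanation was tested. In pri-miR390a, Col DMS replicate 2 and chr2 DMS replicate 1 correlated at r = 0.777, and the other pairs at 0.0850 to 0.224. Positions 58, 189 and 196 had 47.9%, 63.9% and 63.4% in the first and 99.9%, 100.0% and 99.9% in the second. Position 58 also had 11.7% in Col DMS replicate 1, and position 196 had 32.8% in chr2 DMS replicate 2. Whether these libraries shared material was not tested.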

How the results depend on the processing

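Tests with the primer ends left out, a size factor from the mRNAs, all 19 amplicons, regions within a genotype, the fold separation of the mRNAs and single libraries left out of the fold separation were chosen after the data were examined. DESeq2 called 288 A/C and 235 G/T positions between genotypes, where edgeR called 0 of each, 978 and 982 A/C positions above mock in Col and chr2 against edgeR's 344 and 337, 50 and 48 G/T positions above mock against 0, and 52 positions with a differing DMS response against 0; all other settings run on the comparison between genotypes gave 0. Camera with a preset correlation called 3 pri-miRNA sets, and with an estimated one 0. With the replicate block, 0 A/C positions, 0 pri-miRNAs and 0 region groups passed, as without it; same-numbered libraries deviated together by r = 0.0186 over A/C positions, which does not show a pairing, and whether the numbers mark a batch stays open, since the labels do not say and the split by number gave 323 A/C positions by DESeq2. Without 1 DMS library, 0 A/C positions passed above mock in either genotype, 0 to 1 pri-miRNAs passed for the mean (1 higher without Col replicate 2, 1 lower without chr2 replicate 2) and 0 to 1 for the Gini index (1 without chr2 replicate 2), 1 to 6 region groups and 0 to 2 pri-miRNA sets passed by fry. In those fits the lone library is assumed to vary like the others, with fewer residual degrees of freedom. The mean log2 chr2 over Col of region groups ranged from -0.0773 to 0.155 for unpaired, -0.0307 to 0.0886 for paired, -0.116 to 0.359 for terminal loop, -0.131 to 0.0581 for 5' and -0.00593 to 0.128 for 3' positions without 1 library. With a size factor from the mRNAs it was -0.0282 for unpaired and -0.0267 for paired positions. The log2 ratio of the mean rate ranged from -0.0656 to 0.371 in pri-miR166b, -0.303 to 0.658 in pri-miR393b, -0.366 to 0.100 in pri-miR167b, -0.263 to 0.115 in pri-miR160a and -0.0217 to 0.118 in pri-miR166a, where the mRNA size factor gave -0.0729. The Gini difference ranged from -0.00638 to 0.0542 in pri-miR166b and -0.00700 to 0.0462 in pri-miR160a. The chr2 minus Col difference in the area under the curve, -0.00307, was 0.00277 with the unpaired probability, 0.000777 without primer ends, -0.0141 with the mock rate subtracted, the 1 setting in which the pri-miRNA values of the genotypes did not overlap with all libraries kept (exact permutation p = 0.333, the smallest possible), and -0.0168 to 0.0107 without 1 library. Within a genotype, the mean log2 ratio without 1 library ranged from 1.25 to 2.29 for loops over the duplex, 1.03 to 2.10 for loops over the stem, -0.487 to 0.426 for loops over 5' and -0.761 to 0.734 for loops over 3' sequence in Col; in chr2 it was 0.473 to 0.534 over 5' and -0.250 to 0.235 over 3' sequence. The cause of these changes was not tested. The mean A/C rate was higher in chr2 in every setting, at 1.06 to 1.20 times, while the median over positions was 1.00 times, with overlapping libraries (exact permutation p = 1). For single pri-miRNAs, regions and positions, 400 further values kept their direction and side of the threshold, and 18 reversed direction. The 10 named positions were past the threshold under DESeq2 only. The remaining values, of region groups, changed side only with a library left out. Median coverage was at least 54600 in each library, but PCR reads do not show how many molecules were sampled. At this coverage, simulated changes at A/C positions were recovered with a dispersion of 0.01 and not with the spread of these libraries.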

Other observations

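The kind of mismatch also differed between DMS and mock libraries. In the mocks, A-to-T changes made up 37.5% of mismatches at A in Col and 36.8% in chr2, against 72.0% and 63.7% in the Col DMS libraries and 70.1% and 58.5% in the chr2 DMS libraries. At C, C-to-T changes were 71.7% in the Col mock, against 55.3% and 51.1% with DMS, and 69.6% in the chr2 mock, against 50.3% and 42.9%. C-to-G changes were 5.83% against 18.8% and 20.0% in Col, and 5.73% against 18.1% and 21.5% in chr2. Each mock is 1 library, and these shares were not tested. Predicted unpaired A and C of the pri-miRNAs had mean rates of 2.93% ± 0.912 and 2.78% ± 0.619 in Col and of 2.92% ± 0.425 and 3.32% ± 0.530 in chr2 (SD, n = 2 libraries each). Their order was not stable, with 2.29% at A and 3.22% at C in Col replicate 1 and 3.58% and 2.34% in Col replicate 2.

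At 8 positions of UBQ4 both mocks had mismatch rates of 6.73% to 23.4%, and the DMS libraries lower ones of 2.83% to 13.4%. Ubiquitin genes are near-identical copies, so values of UBQ4 are uncertain where reads of another copy were counted, and this was not tested.

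For poor repetition of pri-miRNA A/C rates between replicates, the test of read depth was chosen after the result was seen, and those of template number and plant structure before. Median coverage of pri-miRNAs was 1.208 times that of the mRNAs, which argues against read depth but does not count molecules. Among G/T positions, the internal control, 6.262% in pri-miRNAs exceeded 1% in a single DMS library and stayed under 0.2% elsewhere, mocks included. In mRNAs it was 0.270% (Fisher's exact test p = 9.74e-09, over positions that are not independent). This excess went against the prediction of structure varying between plants as the whole cause. The test does not decide it, since mean G/T rates rose with DMS and the count takes only mismatches rare in the mocks. The share was also small in the pri-miRNAs with the fewest apparent templates: 0% in pri-miR165a, 0.794% in pri-miR393b, 1.15% in pri-miR390a and 2.24% in pri-miR319a. Few cDNA templates per amplicon remain a candidate explanation: their apparent number, itself computed from replicate differences, had a median of 32.6 in pri-miRNAs and 1238 in mRNAs, and 17 pri-miRNA values exceeded 99% in a library, against 0 in mRNAs. The test planned for it did not find the predicted relation, and pri-miR165a, with the lowest number (1.28), had 0% of single-library G/T positions: template number and the share of single-library G/T positions had a Spearman rho of -0.13 across 19 amplicons (permutation p = 0.592; Pearson's r = -0.0508, p = 0.835, and 0.287 without the 2 farthest amplicons) and 0.321 within the 16 pri-miRNAs (permutation p = 0.226; r = 0.411, p = 0.112). Adjusted over both sets, these p-values were 0.592 and 0.452 for rho and 0.835 and 0.225 for r.

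For mRNA rates higher in chr2, the test was chosen after the result was seen. Under a stronger DMS treatment of the chr2 plants, RNAs that repeat well should shift alike. The median chr2 over Col ratio of the 3 mRNAs was 1.14 and that of pri-miR159a 1.04, a quotient of 1.1. Over the 16 pri-miRNAs the median ratio, also without scaling, was 1.10, with 12 higher in chr2 (two-sided exact sign test p = 0.0768). Pri-miR319a counted as higher at a ratio of 1.00. Pri-miR165a counted as lower only because the mock limit left out 5 positions with 99.1% to 100.0% in chr2 replicate 1. This sign test therefore depends on the mock limit. It also treats pri-miRNAs measured in the same DMS libraries as independent, which they are not. The quotient lies at the very edge of the 10% allowed, a bound set after the values were seen. In limma's fit without scaling, the pri-miR159a ratio had an interval of 0.919 to 1.17. That range holds both no shift and the mRNA ratio of 1.14. The quotient therefore does not decide whether the extent of modification differed. A difference in mRNA structure is not excluded, although no single position passed edgeR's test. In either direction, MYC2 passed fry between the genotypes (adjusted p = 0.0157), and UBQ4 (0.499) and MPK3 (0.999) did not. Regrouped libraries were not tested by fry in the mRNAs. On rates without scaling, the split by genotype was the most distant in UBQ4 and MYC2, but not in MPK3.

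A hypothesis stated before its test was that the genotypes differ in pri-miRNA A/C rates. The split by genotype was the most distant of the 3 splits of the 4 DMS libraries in 4 of 16 pri-miRNAs (two-sided exact binomial p = 0.602), against 7 for the split by replicate number and 5 for the crossed one. The binomial test treats the 16 pri-miRNAs as independent, although all were measured in the same 4 libraries. The distances gave no evidence for the hypothesis.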
